A study of Mus musculus with 12 samples.

How the data were processed

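Retinal RNA recovered by immunoprecipitation of HA-tagged ribosomes was sequenced from C57BL/6 mice at postnatal day 3 (6 libraries) and day 9 (6 libraries). Per the labels, the cell type is retinal pericytes, tamoxifen was injected on days 1 and 2, RNA was purified with a micro-scale column kit after immunoprecipitation through the HA tag, and libraries were made with a stranded NuGEN mRNA kit. The driver that switches on the tag is not given in the sources used here, and libraries of RNA before immunoprecipitation were not analysed here, so enrichment over whole retina was not measured.

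The deposited values are RSEM expected counts per gene and library, estimated read counts that were not scaled to depth; 15.9% of them are not whole numbers. Per the submitters' processing notes, FastQC, Trim Galore, STAR, RSEM and limma were used with the mouse build mm10; their versions, roles and the annotation are not given in the sources used here. Expected counts share reads of near-identical genes by a model, which leaves globin, crystallin, opsin, ribosomal protein and mitochondrial genes less certain. Each table has 53090 gene rows, of which 0 name no gene and 240 repeat a symbol; of rows with the same symbol the most abundant was used for lists and named genes. Coordinates are those of RefSeq on GRCm38.p6, the assembly that mm10 names, matched by symbol for 16226 tested genes and by an older symbol for 376; 2036 stayed without a match.

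Groups were taken from the age in the labels, and replicates were numbered in deposition order, so a replicate number does not pair libraries. The labels of P9 replicates 5 and 6 carry sample names crossed between them; both are P9, so no comparison of the ages depends on it. The labels name no litter, sex or batch.

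Expected counts were rounded to whole numbers. Genes with low counts were removed by filterByExpr (18638 tested, 34452 removed), libraries were scaled by TMM, and the ages were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The log2 fold change is P9 over P3, and its standard error is its size divided by the square root of the F statistic. CPM values are TMM-scaled, given as mean ± SD over 6 libraries. Library totals ran from about 26840000 to 37776000 counts. With the TMM factors a gene at 1 CPM rests on about 25.8 to 38.5 counts per library, and lower genes carry wider relative errors. Principal components and correlations used log2 CPM with a prior count of 2. Tables were read with data.table version 1.17.8.

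The lists, 36 in all with 734 genes (731 in the data, 712 tested), the named-gene rule, the tests and the alternatives were fixed before the data were examined, except where said. The lists cover mural cells (pericyte identity, smooth muscle contractile, basement membrane, fibrillar collagen and matrix remodelling), processes (cell cycle, cell cycle exit, PI3K, PDGF and FGF, Notch, TGF-beta and BMP, angiogenic factors, Wnt, ion channels and transporters, oxidative phosphorylation, glycolysis and hypoxia, ribosomal proteins, interferon, sterol synthesis), other cells (endothelial, fibroblast, astrocyte, Müller glia, retinal progenitor, rod, cone, bipolar, amacrine, horizontal, ganglion cell, microglia, pigment epithelium, erythroid, lens) and quality (immediate early and heat shock, mitochondrially encoded, sex linked). Each list with at least 5 tested genes was tested with camera of limma 3.58.1 (two-sided, preset correlation of 0.01, adjusted over the lists). The adjusted p with a correlation estimated per list is given beside it, and member counts are also given adjusted over the list alone. For mural, other-cell and quality lists the CPM was summed per library and compared on the log2 scale with an exact two-sided permutation test of 6 against 6 libraries (924 assignments), adjusted over 22 classes.

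The rule named 12 genes of mural cells, proliferation and PI3K signalling whatever their values. It added the 10 largest rises and the 10 largest falls among called genes with a mean of at least 10 CPM, no overlap between the ages, a symbol that is no model or pseudogene name and no place on an other-cell or quality list. Per list, it named the 3 called members with the smallest adjusted p, or the most abundant members up to 2 where fewer than 2 were called. Some genes that this rule names are not reported here, and no others took their place. Tbx2, Ndufa2, Stat2, Dbi and Otx2, each the single exception of its list, and the genes named only in the closing section were chosen after their values were seen.

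The procedure was tested on simulated counts drawn from the mean level of each gene over the 12 libraries, their sizes and the fitted dispersions. Among 18270 genes tested for P9 against P3, 200 were changed by known amounts, besides a raised list. edgeR recovered 40% of the 1.5-fold, 60% of the 2-fold, 82% of the 4-fold and 94% of the 8-fold changes, and 5.77% of its calls were false. DESeq2 had 17.3% and limma-voom 4.03% false calls. The simulated genes varied independently and far fewer were changed than were called in the real data, so these rates need not hold there.

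The alternatives were median-ratio and upper-quartile factors, library totals, factors without other-cell genes, no low-count filter or a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom with and without quality weights, a robust fit, each library left out, the rod, progenitor or pericyte list mean as a covariate, 1 surrogate variable from sva 3.50.0, an adjusted p under 0.01, the estimated list correlation, fry, lists without shared genes, and a mean of log2(CPM + 1) for the classes. Chosen after seeing the data were leaving out P3 replicates 4 and 5, leaving out P9 replicates 5 and 6, and the Y-linked or lens mean as a covariate. No paired analysis was possible because the labels give no shared replicate numbers.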

Results

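The libraries hold RNA recovered by immunoprecipitation of ribosomes carrying an HA epitope tag, from retinas of C57BL/6 mice. How much of it was bound to tagged ribosomes was not measured. Long noncoding RNAs were present too, with Miat at a mean of 5844 CPM and Malat1 at 1271 CPM at P3. The labels name the cells as retinal pericytes, the mural cells that wrap capillaries. Tamoxifen was given on postnatal days 1 and 2. Retinas were taken on day 3 (P3) or day 9 (P9), a period in which the retinal vessels grow and remodel. The time from tamoxifen to harvest was therefore longer at P9, and its effect cannot be separated from that of age. There were 6 libraries per age, 12 in total. Their totals were about 29363000, 28823000, 26840000, 33514000, 32313000 and 33061000 expected counts for P3 replicates 1 to 6. For P9 replicates 1 to 6 they were about 34321000, 37776000, 36850000, 32507000, 33734000 and 34034000. The 10 most abundant genes took between 3.44% and 5.18% of a library. The labels do not say whether a library holds a single animal or whether libraries of an age came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. Each library was counted as a separate sample. The series asks which transcripts mark mural cells at each age, and P9 against P3 is the comparison its design holds.

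Between P3 and P9, 24 of 30 tested genes of pericytes and 15 of 22 of contractile mural cells rose and all 40 proliferation genes fell, together with wide changes in transcripts of other retinal cells. With an estimated correlation between genes none of these 3 lists was called (adjusted p of 0.369, 0.369 and 0.149), and the summed CPM of the contractile genes did not pass. Of 18638 genes tested, 4868 rose and 4779 fell, together 51.8%, and 8991 did not pass an adjusted p of 0.05. At least a 2-fold change was called for 3357 genes, 1864 upward and 1493 downward. For 5910 genes (31.7%) the 6 values of an age did not overlap with those of the other, against 0.216% by chance. The first principal component held 51.5% of the variance and separated the ages. Along it, P3 replicates 4 and 5 (scores -45.6 and -46.04) and P9 replicate 3 (46.7) lay nearest to the other age. The correlation of log2 CPM was 0.952 to 0.970 between P3 libraries, 0.960 to 0.974 between P9 libraries and 0.882 to 0.945 between ages. The closest pairs were P3 replicates 4 and 5 (0.970) and P9 replicates 5 and 6 (0.974). The labels do not say whether the libraries of these pairs share an origin. Without P3 replicates 4 and 5, a choice made after seeing the data, 5113 genes rose and 4804 fell. With the mean level of the retinal progenitor markers in the model, edgeR called 0 genes (323 at an unadjusted p under 0.05; other tools were not run with it), and age shared 97.5% of the variance of that mean.

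**Figure D1:**
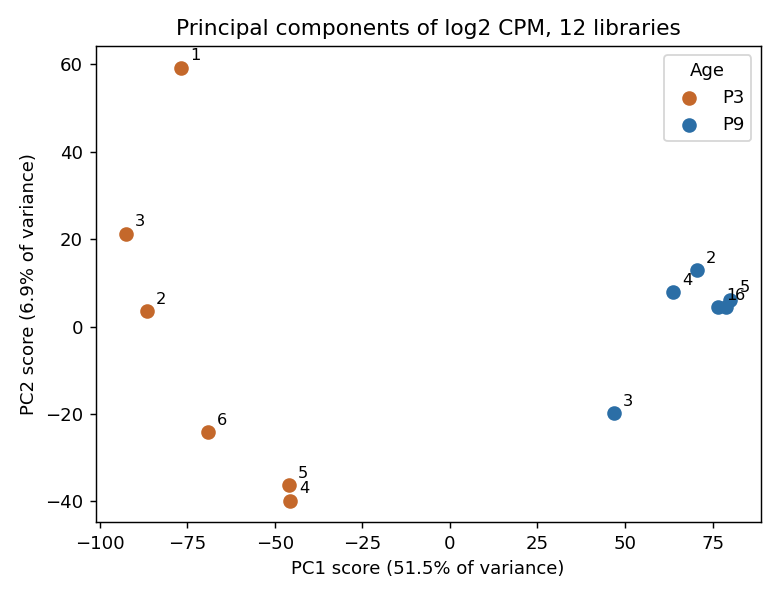
Scores of the 12 libraries on the first principal component (x axis, 51.5% of the variance) and the second (y axis, 6.93%) of log2 CPM; each point is a library, coloured by age and marked with its replicate number. All P3 libraries lie at or below -45.6 on the first component and all P9 libraries at or above 46.7.

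Pericyte genes rose at P9. Of 30 tested genes of the pericyte identity list, 24 rose, 1 fell and 5 did not pass (25 and 1 adjusted over the list alone), with a median log2 fold change of 1.996. Pdgfrb (ENSMUSG00000024620.11, chromosome 18, 61045127 to 61085067 in mm10), the receptor through which endothelial PDGF-B recruits pericytes, went from 116 ± 56.2 to 698 ± 209 CPM (SD, n = 6 per age; log2 fold change 2.59 ± 0.30, SE; adjusted p = 4.92e-06). Rgs5 (ENSMUSG00000026678.10, chromosome 1, 169655501 to 169695813), a regulator of G-protein signalling used as a pericyte marker, rose from 395 ± 272 to 2698 ± 762 CPM. Cspg4 (ENSMUSG00000032911.6, chromosome 9, 56865104 to 56899870), which encodes the NG2 proteoglycan, rose from 19.2 ± 11.6 to 84.1 ± 20.8 CPM. Kcnj8 (ENSMUSG00000030247.9, chromosome 6, 142564837 to 142571614) and Abcc9 (ENSMUSG00000030249.15, chromosome 6, 142587862 to 142702766) encode the pore and the regulatory subunit of an ATP-sensitive potassium channel. Kcnj8 rose from 5.54 ± 4.03 to 76.5 ± 25.4 CPM, 13.7-fold, and Abcc9 from 20.9 ± 13.2 to 247 ± 92.2 CPM, 11.8-fold. Vtn, which encodes vitronectin, rose 23.4-fold to 118 ± 33.9 CPM, Notch3 (ENSMUSG00000038146.7, chromosome 17, 32120820 to 32166896), the Notch receptor of mural cells, 2.84-fold and Rgs4 2.36-fold. The member that fell was Tbx2, a transcription factor also expressed in neural retina, from 223 ± 27.03 to 183 ± 20.4 CPM. Like Ndufa2, Stat2, Dbi and Otx2 on other lists, Tbx2 was named after its values were seen. Its call was lost without P3 replicate 2 or P9 replicate 4 or 5 (adjusted p of 0.0521, 0.0513 and 0.0521). The list passed the camera test (adjusted p = 2.91e-08, and adjusted p = 0.369 with an estimated correlation). Its summed CPM went from 1322 ± 435 to 5159.8 ± 1317, 3.97-fold (exact permutation test, two-sided, adjusted p = 0.00366). This was 0.132% of the counts at P3 and 0.516% at P9. The rod list took 0.312% and 1.80%, the lens list 0.897% and 0.0334%, and the endothelial list 0.102% and 0.0810%. The lists differ in size, so these are not shares of cells. In the same libraries the summed rod photoreceptor markers were 5.83-fold higher and the summed retinal progenitor markers 1.56-fold lower at P9. The median log2 fold changes of these 2 lists were 3.18 and -1.93. How much other retinal cells contributed to the members that rose was not measured.

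**Figure D2:**
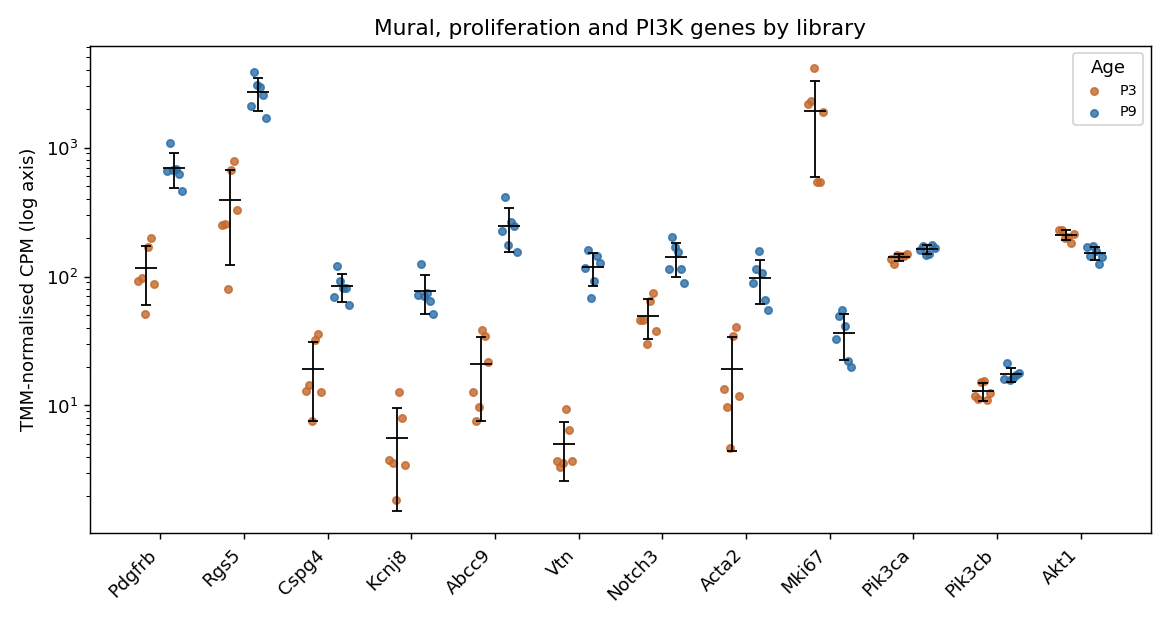
TMM-normalised CPM on a log axis for single genes (x axis); each point is a library (6 at P3, 6 at P9), and the bars give the mean and SD, with lower ends that would pass below 0 drawn short. Pdgfrb goes from a mean of 116 to 698 CPM and Mki67 from 1926 to 36.8 CPM, while Pik3ca goes from 142 to 162 CPM.

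Most contractile genes of smooth muscle rose at P9. Of 22 tested genes, 15 rose, 1 fell and 6 did not pass (16 and 1 adjusted over the list alone), with a median log2 fold change of 1.27. Acta2 (ENSMUSG00000035783.8, chromosome 19, 34240336 to 34255585), smooth muscle actin, went from 19.1 ± 14.7 to 98.1 ± 37.04 CPM (SD, n = 6 per age; log2 fold change 2.36 ± 0.44, SE; adjusted p = 0.000414). Mylk, the myosin light chain kinase, rose 2.59-fold to 202 ± 16.7 CPM, and Itga8, an integrin subunit, 6.10-fold from 2.86 ± 0.975 CPM. The member that fell was Flna, the actin crosslinker filamin A, from 1177 ± 236 to 557 ± 113 CPM. The camera adjusted p was 0.00126, and the adjusted p = 0.369 with an estimated correlation. The summed CPM of the list, to which Flna contributed most, showed no difference past the threshold (1865 ± 183 and 1852 ± 299.6; exact permutation adjusted p = 0.851), whereas the mean of log2(CPM + 1) over its members was higher at P9 by 1.07. Endothelial and rod photoreceptor markers also differed between these libraries.

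Components of the vascular basement membrane changed in both directions, with 11 of 20 tested genes rising, 5 falling and 4 not passing (the same adjusted over the list alone). Nid2, which encodes nidogen 2, rose 4.02-fold from 11.9 ± 3.41 to 47.7 ± 11.98 CPM (SD, n = 6 per age), and Vtn stands on this list too. Lamb2, the laminin beta 2 chain, fell from 95.6 ± 15.3 to 41.2 ± 4.64 CPM. The list's median log2 fold change was 0.88 (camera adjusted p = 0.0322, and adjusted p = 0.480 with an estimated correlation), and its call was lost without P9 replicate 3 (adjusted p = 0.0665). Its summed CPM was 4219.5 ± 545 and 5302 ± 989.8 (exact permutation adjusted p = 0.0556); without P3 replicate 4, P3 replicate 5 or P9 replicate 6 that difference passed (adjusted p of 0.0265, 0.0476 and 0.0149). Among genes of fibrillar collagen and matrix remodelling, 10 of 24 rose, 4 fell and 10 did not pass (the same adjusted over the list alone). Col5a3, a fibril-forming collagen chain, rose 4.08-fold to 56.5 ± 11.2 CPM, Loxl2, a collagen-crosslinking oxidase, 3.28-fold to 89.6 ± 25.6 CPM and Timp3, an inhibitor of metalloproteinases, 2.98-fold to 88.05 ± 21.5 CPM. The camera test of this list did not pass (adjusted p = 0.0658, and adjusted p = 0.478 with an estimated correlation). It passed without P3 replicate 1 or without P9 replicate 1, 5 or 6 (adjusted p of 0.00923, 0.0444, 0.0499 and 0.0322), and its sum rose 1.35-fold (exact permutation adjusted p = 0.0179). The fibroblast gene Col14a1 stood at 41.2 CPM in P3 replicate 1. Markers of other cells moved in the same libraries. The endothelial list had a median log2 fold change of 0.95 and a sum 1.25-fold lower at P9. The rod sum was 5.83-fold higher and the progenitor sum 1.56-fold lower, with median log2 fold changes of 3.18 and -1.93.

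Genes of ion channels and transporters rose: 22 of 29 rose, 3 fell and 4 did not pass (the same adjusted over the list alone), with a median log2 fold change of 1.09. Cacnb2, an auxiliary subunit of voltage-gated calcium channels, went from 18.1 ± 3.89 to 121 ± 24.7 CPM (SD, n = 6 per age; log2 fold change 2.74 ± 0.17, SE; adjusted p = 2.86e-08). Kcnma1, the large-conductance calcium-activated potassium channel, rose 5.30-fold to 331 ± 45.5 CPM, and Kcnk3, a background potassium channel, 5.61-fold to 22.6 ± 4.11 CPM. Kcnj8 and Abcc9 belong to this list as well. The camera adjusted p was 2.00e-08, and the adjusted p = 0.149 with an estimated correlation. Retinal neurons express several of these channels, and the median log2 fold changes of the rod and bipolar cell lists in the same libraries were 3.18 and 3.97.

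Every proliferation gene on the cell cycle list fell at P9. All 40 tested genes fell (40 adjusted over the list alone), and the median level was 4.63-fold lower at P9. Mki67 (ENSMUSG00000031004.8, chromosome 7, 135689784 to 135716450), the Ki-67 proliferation marker, went from 1926 ± 1335 to 36.8 ± 14.3 CPM (SD, n = 6 per age; log2 fold change -5.71 ± 0.53, SE; adjusted p = 6.53e-07). Top2a, the topoisomerase of dividing cells, fell from 458 ± 156 to 36.2 ± 9.17 CPM and Cenpf, a kinetochore protein, from 189.8 ± 57.1 to 10.4 ± 2.86 CPM. E2f1, a transcription factor of S-phase entry, was 12.3-fold lower at P9. The camera adjusted p was 1.28e-35, and the adjusted p = 0.149 with an estimated correlation. Among genes of cell cycle exit, 10 of 20 fell, 4 rose and 6 did not pass (the same adjusted over the list alone). This list was lower at P9 by camera (adjusted p = 0.0396, and adjusted p = 0.316 with an estimated correlation), a call lost without P9 replicate 4 (adjusted p = 0.0539). Gadd45g, a growth arrest gene, fell from 49.9 ± 6.97 to 8.53 ± 2.06 CPM, the kinase inhibitor gene Cdkn2c was 3.69-fold lower and the retinoblastoma relative Rbl1 3.32-fold lower. Retinal progenitor markers, which label dividing cells of the neural retina, had a median log2 fold change of -1.93 in the same libraries. With their mean in the model, the median of the cell cycle list was 0.081 and its camera adjusted p 0.898; the median of the pericyte list in that model was 0.11.

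Genes of the PI3K pathway moved in both directions. Of 34 tested genes, 10 rose, 12 fell and 12 did not pass (the same adjusted over the list alone). The list was not called by camera (median log2 fold change -0.041, camera adjusted p = 0.372, and adjusted p = 0.478 with an estimated correlation), whereas fry called it lower (fry adjusted p = 0.00179). Pik3cb (ENSMUSG00000032462.14, chromosome 9, 99038402 to 99140235), which encodes the catalytic subunit p110 beta, rose from 12.9 ± 1.98 to 17.5 ± 2.14 CPM (SD, n = 6 per age; log2 fold change 0.44 ± 0.12, SE; adjusted p = 0.00608). Pik3ca (ENSMUSG00000027665.13, chromosome 3, 32397065 to 32466112), the p110 alpha subunit, rose from 142 ± 8.96 to 162 ± 12.4 CPM (log2 fold change 0.20 ± 0.070, SE; adjusted p = 0.0271). That call was lost without P3 replicate 1 or 2 or without P9 replicate 2, 5 or 6 (adjusted p of 0.0525, 0.0633, 0.0602, 0.0643 and 0.0548). Akt1 (ENSMUSG00000001729.14, chromosome 12, 112653821 to 112674884), a kinase downstream of them, fell from 209 ± 18.3 to 152 ± 18.8 CPM. Inpp4b, an inositol lipid phosphatase, rose 2.67-fold, while the phosphatase gene Inppl1 was 2.68-fold lower and the transcription factor gene Foxo4 2.45-fold lower at P9. Rod and progenitor markers shifted in the same libraries, as given for those lists.

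Notch pathway genes fell at P9 in most cases. Of 20 tested, 12 fell, 4 rose and 4 did not pass (the same adjusted over the list alone; median log2 fold change -0.49; camera adjusted p = 1.76e-05, and adjusted p = 0.109 with an estimated correlation). Notch1 fell from 713 ± 74.02 to 136 ± 30.8 CPM, its ligand gene Dll1 was 6.69-fold lower and the glycosyltransferase gene Lfng 4.07-fold lower, while Notch3 rose as given with the pericyte genes. Dll1 is also on the progenitor list, whose median log2 fold change was -1.93. Among Wnt pathway genes, 14 of 26 fell, 7 rose and 5 did not pass (the same adjusted over the list alone; camera adjusted p = 0.0447, lower at P9, and adjusted p = 0.478 with an estimated correlation). Leaving out P3 replicate 4 or 5 or P9 replicate 1, 4 or 6 ended the Wnt call (adjusted p of 0.0749, 0.0790, 0.0584, 0.0611 and 0.0610). Sfrp1, a secreted Wnt antagonist, fell from 47.9 ± 7.44 to 9.90 ± 5.69 CPM, the ligand gene Wnt7a was 24.3-fold lower from 3.41 ± 1.06 CPM, and the transcription factor gene Tcf7l2 was 2.58-fold lower.

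Other growth factor pathways changed gene by gene without a shift of the list. In the TGF-beta and BMP list 11 genes rose, 11 fell and 9 did not pass out of 31 (the same adjusted over the list alone). Its median and mean log2 fold changes were 0.099 and 0.15, with the camera direction lower (adjusted p = 0.871, and adjusted p = 0.937 with an estimated correlation). Tgfb2, a TGF-beta ligand, rose 2.32-fold to 212 ± 28.2 CPM, and the signal transducer genes Smad2 and Smad5 were 1.89-fold and 1.64-fold lower at P9. In the PDGF and FGF list 9 genes rose, 8 fell and 4 did not pass out of 21 (10 and 8 adjusted over the list alone). Its median and mean were 0.19 and 0.11, with the camera direction lower (adjusted p = 0.875, and adjusted p = 0.937 with an estimated correlation). Spry2, a feedback inhibitor of receptor tyrosine kinases, rose 2.17-fold, while the FGF receptor genes Fgfr1 and Fgfrl1 were 1.94-fold and 2.92-fold lower. Of 28 angiogenic factors, 8 rose, 7 fell and 13 did not pass (the same adjusted over the list alone; median 0.11; camera adjusted p = 0.829, and adjusted p = 0.932 with an estimated correlation). Igf1, a growth factor, rose 2.63-fold to 30.4 ± 6.62 CPM, and Mdk, which encodes midkine, and Sema3f, a semaphorin, were 2.69-fold and 1.87-fold lower.

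Genes of oxidative phosphorylation rose almost throughout, with 35 of 36 rising (the same adjusted over the list alone) and a median 1.58-fold higher level. The exception was Ndufa2, at 14.8 ± 2.96 and 17.3 ± 1.90 CPM (adjusted p = 0.171). Ndufb9, a complex I subunit, rose from 22.5 ± 4.16 to 47.7 ± 7.35 CPM, Cox6c, of complex IV, 1.68-fold and Uqcrc1, of complex III, 1.40-fold. The camera adjusted p was 2.00e-08, and the adjusted p = 0.369 with an estimated correlation. Of 30 glycolysis and hypoxia genes, 15 rose, 5 fell and 10 did not pass (the same adjusted over the list alone; camera adjusted p = 0.0406, and adjusted p = 0.413 with an estimated correlation), a call lost without P9 replicate 3 (adjusted p = 0.0746). Hk1, a hexokinase, rose 4.15-fold to 395 ± 62.6 CPM and Aldoc, a brain aldolase, 3.21-fold, whereas the glucose transporter gene Slc2a1 fell from 326 ± 15.9 to 195 ± 27.96 CPM. Of 22 interferon response and antigen presentation genes, 12 rose, 1 fell and 9 did not pass (the same adjusted over the list alone; median log2 fold change 0.78; camera adjusted p = 0.00340, and adjusted p = 0.369 with an estimated correlation). Ifitm3, an antiviral membrane protein, rose 5.86-fold to 30.5 ± 6.50 CPM, B2m, the light chain of class I antigen-presenting molecules, 2.77-fold and Oasl2 2.20-fold. The member that fell was the transcription factor gene Stat2, from 112 ± 13.4 to 87.5 ± 5.23 CPM. Rod markers, with a median log2 fold change of 3.18, rose in the same libraries.

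Of 24 sterol synthesis genes, 11 fell, 3 rose and 10 did not pass (the same adjusted over the list alone), and the list was not called by camera on the filtered edgeR values (camera adjusted p = 0.0666, and adjusted p = 0.446 with an estimated correlation). It was called lower without a low-count filter, with limma-voom and with its quality weights, without P3 replicate 2 (adjusted p = 0.0499), without P9 replicates 5 and 6, a choice made after seeing the data, and by fry (adjusted p = 0.000424). Srebf2, a main transcription factor of sterol synthesis, fell from 179 ± 17.3 to 111 ± 3.48 CPM, and Lss, lanosterol synthase, was 1.48-fold lower. Of 40 ribosomal protein genes, 8 fell and 32 did not pass (3 fell adjusted over the list alone). Rplp0 was 1.51-fold lower, Rps19 1.42-fold lower and Rps9 1.35-fold lower; these genes share reads with many processed copies, so their levels are uncertain. The ribosomal list was not called by camera on the filtered edgeR values (camera adjusted p = 0.106, and adjusted p = 0.781 with an estimated correlation). It was called lower without a low-count filter, with limma-voom and with its quality weights, and without P3 replicate 2, P3 replicate 3 or P9 replicate 1 (adjusted p of 0.0416, 0.0253 and 0.0327). Rod and progenitor markers shifted in these libraries too, with sums 5.83-fold higher and 1.56-fold lower at P9. Their median log2 fold changes were 3.18 and -1.93.

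**Figure D3:**
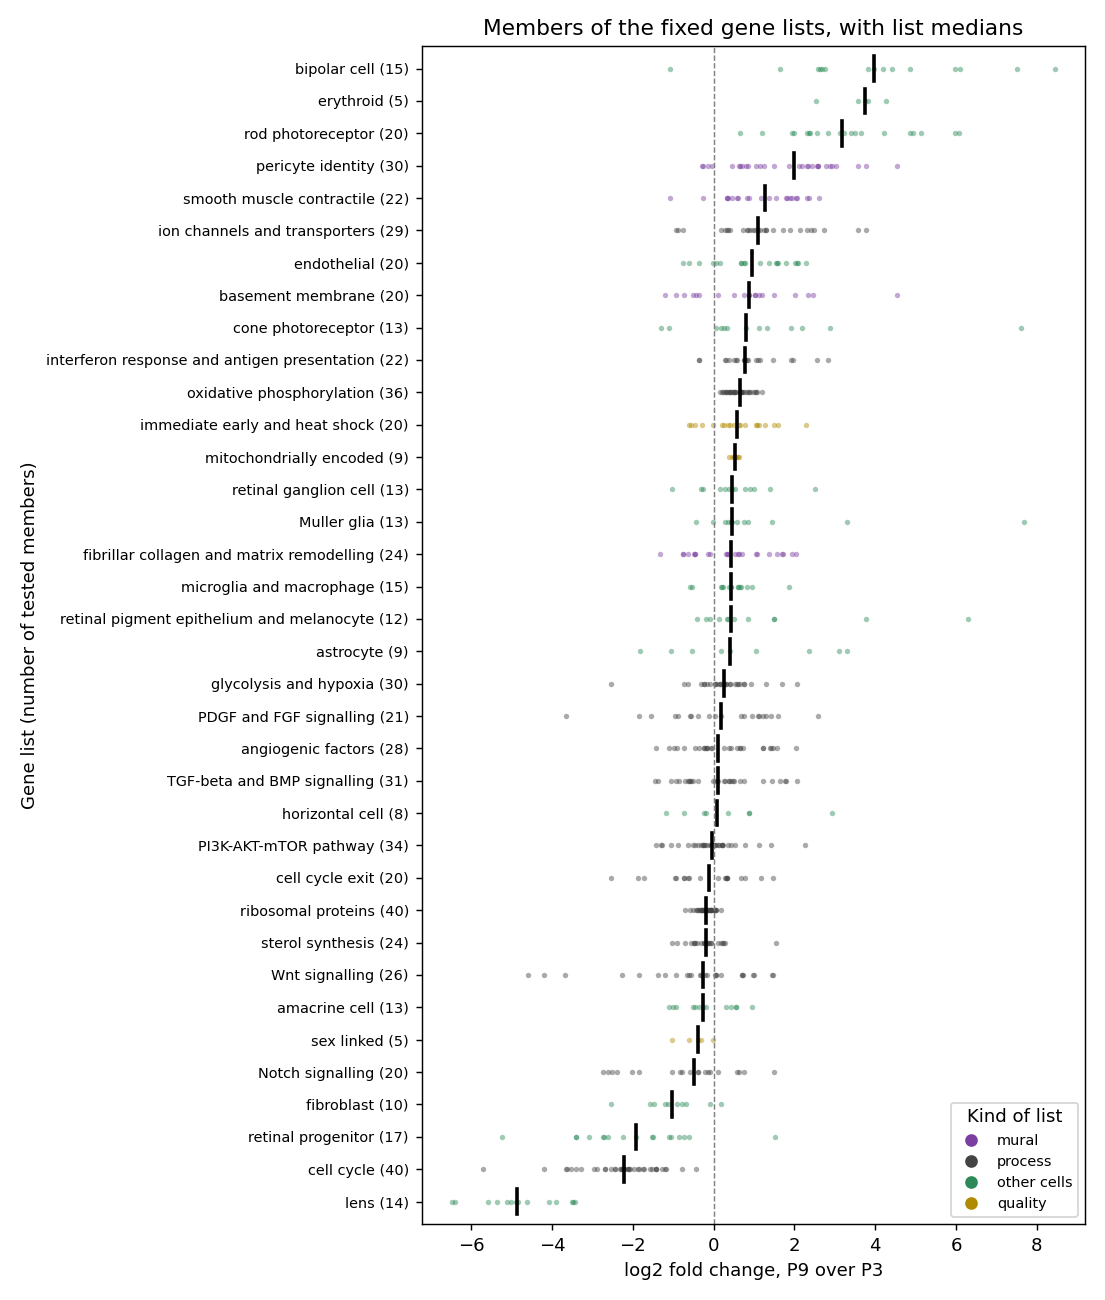
Log2 fold change of P9 over P3 (x axis) for the tested members of the 36 fixed gene lists (y axis); each point is a gene, and the bars mark the list medians. Medians run from -4.86 for lens to 3.97 for bipolar cells, with the pericyte identity list at 1.996 and the cell cycle list at -2.21.

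Transcripts of photoreceptors and bipolar cells, neurons that mature during these days, rose at P9. All 20 rod genes rose (20 adjusted over the list alone; median log2 fold change 3.18; camera adjusted p = 1.68e-18, and adjusted p = 0.175 with an estimated correlation). Sag, rod arrestin, went from 232 ± 89.2 to 2181 ± 708 CPM, Slc24a1, the rod sodium-calcium exchanger, rose 67.2-fold and the phosphodiesterase gene Pde6a 30.9-fold. The summed rod markers went from 3122 ± 1026 to 17953 ± 4635 CPM, or from 0.312% to 1.80% of the counts. Of 13 cone genes, 8 rose, 2 fell and 3 did not pass (the same adjusted over the list alone; camera adjusted p = 0.00174, and adjusted p = 0.369 with an estimated correlation). Arr3, cone arrestin, rose 7.35-fold and the phosphodiesterase gene Pde6c 2.48-fold. Opn1mw, an opsin gene near 0 at P3, rose from 0.0525 ± 0.0965 to 11.2 ± 6.63 CPM; its log2 fold change of 7.60 became 9.36 without P3 replicate 5. Of 15 bipolar cell genes, 14 rose and 1 fell (the same adjusted over the list alone; median log2 fold change 3.97; camera adjusted p = 5.94e-27), a call that held with an estimated correlation (adjusted p = 0.0150). Grm6, the glutamate receptor of ON bipolar cells, rose 351-fold from 1.54 ± 0.970 to 552 ± 59.5 CPM, Gpr179 15.7-fold and Isl1 6.02-fold. The member that fell was Otx2, which photoreceptor precursors also express, from 1033 ± 68.4 to 490.1 ± 76.9 CPM.

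Retinal progenitor genes fell and inner neurons showed mixed changes. Of 17 retinal progenitor genes, 16 fell and 1 rose (the same adjusted over the list alone; camera adjusted p = 2.87e-17), a call that held with an estimated correlation (adjusted p = 0.0150). Lhx2, a transcription factor of the developing eye, fell from 106 ± 2.63 to 37.5 ± 5.42 CPM. Of 13 amacrine cell genes, 7 fell, 3 rose and 3 did not pass (the same adjusted over the list alone; camera adjusted p = 0.220, and adjusted p = 0.478 with an estimated correlation). Pax6, shared with the progenitor list, was 2.14-fold lower, the transcription factor gene Tfap2a 2.02-fold lower and Gad2, a GABA-synthesising enzyme, 1.90-fold lower. Of 13 ganglion cell genes, 7 rose, 2 fell and 4 did not pass (the same adjusted over the list alone; camera adjusted p = 0.0441, and adjusted p = 0.413 with an estimated correlation), a call lost without P3 replicate 4 or 5 (adjusted p of 0.0554 and 0.0590). Nefh, the heavy neurofilament chain, rose 5.74-fold, Thy1 2.63-fold and the glutamate transporter gene Slc17a6 1.87-fold. Of 8 horizontal cell genes, 3 rose, 2 fell and 3 did not pass (the same adjusted over the list alone; camera adjusted p = 0.588, and adjusted p = 0.657 with an estimated correlation). Calb1, calbindin, rose 7.59-fold and Sept4 1.82-fold, and the transcription factor gene Onecut2 was 2.27-fold lower.

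Vascular and glial markers also changed. Of 20 endothelial genes, 8 rose, 1 fell and 11 did not pass (the same adjusted over the list alone; camera adjusted p = 0.0372, and adjusted p = 0.568 with an estimated correlation), a call lost without P3 replicate 4 or P9 replicate 2 (adjusted p of 0.0631 and 0.0540). Esam, an adhesion molecule of endothelial junctions, rose 4.28-fold from 8.11 ± 2.68 to 34.8 ± 7.74 CPM and Ramp2 4.05-fold. The member that fell was Kdr, a VEGF receptor that retinal progenitors also express, from 926 ± 79.5 to 603 ± 30.7 CPM. The sum over the list, to which Kdr contributed most, was lower at P9 (1016 ± 57.2 and 809.5 ± 51.3 CPM; exact permutation adjusted p = 0.00366), whereas its mean log2(CPM + 1) was higher by 0.79. Of 13 Müller glia genes, 9 rose, 1 fell and 3 did not pass (10 and 1 adjusted over the list alone; camera adjusted p = 0.00340, and adjusted p = 0.413 with an estimated correlation). Abca8a rose 205-fold to 104 ± 34.04 CPM, Aqp4, the water channel of glial endfeet, 9.78-fold and Car14, a carbonic anhydrase, 2.71-fold, while Dbi fell from 99.6 ± 17.9 to 73.8 ± 8.49 CPM. Of 9 astrocyte genes, which include Aqp4, 4 rose, 2 fell and 3 did not pass (the same adjusted over the list alone; camera adjusted p = 0.372, and adjusted p = 0.478 with an estimated correlation). Aldh1l1 rose 5.14-fold, and Fabp7, which progenitors also express, fell from 129.96 ± 19.5 to 36.8 ± 12.3 CPM. The astrocyte sum was 1.33-fold lower at P9 (exact permutation adjusted p = 0.0102), whereas the mean log2(CPM + 1) was higher by 0.56.

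Markers of lens and blood differed widely by age. All 14 lens genes fell (14 adjusted over the list alone, median log2 fold change -4.86, camera adjusted p = 1.23e-08, and adjusted p = 0.369 with an estimated correlation). Their sum went from 8966 ± 2929 to 334 ± 542 CPM. The difference between the age means of the log2 sums was -5.80, and -6.44 without P9 replicate 2. Mip, the lens fibre membrane protein, fell from 195 ± 52.01 to 2.29 ± 1.40 CPM. The crystallin genes Cryba2 and Crybb2 had log2 fold changes of -6.48 and -4.90, and -7.18 and -5.52 without P9 replicate 2. All 5 tested erythroid genes rose (5 adjusted over the list alone; camera adjusted p = 0.0138, and adjusted p = 0.413 with an estimated correlation). The globin genes Hba-a1, Hbb-bs and Hbb-bt, near-identical to neighbouring copies and so uncertain in their split, rose 11.9-fold, 14.04-fold and 19.4-fold. Without P9 replicate 2 the log2 fold changes of Hbb-bs and Hbb-bt went from 3.81 and 4.28 to 3.12 and 3.64.

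Of 12 genes of pigment epithelium and melanocytes, 5 rose and 7 did not pass (the same adjusted over the list alone; camera adjusted p = 0.0322, and adjusted p = 0.413 with an estimated correlation). Rpe65, the retinoid isomerase, rose to 5.07 ± 1.88 CPM, the transthyretin gene Ttr 13.7-fold and Rgr 2.82-fold. Of 15 microglia and macrophage genes, 6 rose and 9 did not pass (the same adjusted over the list alone; camera adjusted p = 0.188, and adjusted p = 0.657 with an estimated correlation), with Lyz2 up 3.64-fold and Ctss 1.93-fold. Of 10 fibroblast genes, 2 fell and 8 did not pass (1 fell adjusted over the list alone; camera adjusted p = 0.569, and adjusted p = 0.813 with an estimated correlation). Ogn was 2.20-fold lower. Col14a1 stood at 41.2 CPM in P3 replicate 1 and at most 1.86 CPM in any other P3 library, and its log2 fold change of -2.54 became 0.23 without that library (adjusted p = 0.593). Its call was also lost without any single P9 library (adjusted p from 0.0557 without P9 replicate 3 to 0.0718 without P9 replicate 5) and with limma-voom (log2 fold change -0.58, adjusted p = 0.572).

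By summed CPM, 17 of 22 marker and quality classes differed by age (exact permutation test over 924 assignments, two-sided, smallest possible p 0.00216), 12 higher and 5 lower at P9. Ganglion cell, microglia and horizontal cell sums were 1.62-fold, 1.37-fold and 1.20-fold higher, and the amacrine sum was 1.39-fold lower. Of 20 immediate early and heat shock genes, which respond to tissue handling, 8 rose, 2 fell and 10 did not pass (the same adjusted over the list alone; camera adjusted p = 0.112, and adjusted p = 0.413 with an estimated correlation). Ier3 rose 2.84-fold, Egr3 4.86-fold and Junb 2.40-fold, and the sum of this list was 331 ± 27.6 and 335 ± 12.4 CPM (exact permutation adjusted p = 0.764). Of 9 tested mitochondrially encoded genes, which share reads with nuclear copies and are therefore uncertain, 7 rose and 2 did not pass (8 rose adjusted over the list alone; camera adjusted p = 0.116, and adjusted p = 0.657 with an estimated correlation). mt-Nd6 rose 1.53-fold, mt-Nd5 1.46-fold and mt-Nd2 1.51-fold, the last a call lost without P3 replicate 3 or P9 replicate 5 or 6 (adjusted p of 0.0526, 0.0619 and 0.0574). The mitochondrial sum was 1.46-fold higher (exact permutation adjusted p = 0.0448); without P3 replicate 1, 2 or 3 or P9 replicate 1, 4, 5 or 6 it did not pass (adjusted p from 0.0644 without P9 replicate 4 to 0.0952 without P9 replicate 5). None of the 5 sex-linked genes passed (the same adjusted over the list alone; camera adjusted p = 0.969, and adjusted p = 0.978 with an estimated correlation). Xist was at 3583 ± 7009 CPM at P3 and 1745 ± 2651 CPM at P9, and the Y-linked Eif2s3y at 216 ± 173 and 173 ± 117 CPM. The P3 mean of Xist rests mostly on replicate 3, without which its log2 fold change went from -1.04 to 1.15, neither past the threshold.

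**Figure D4:**
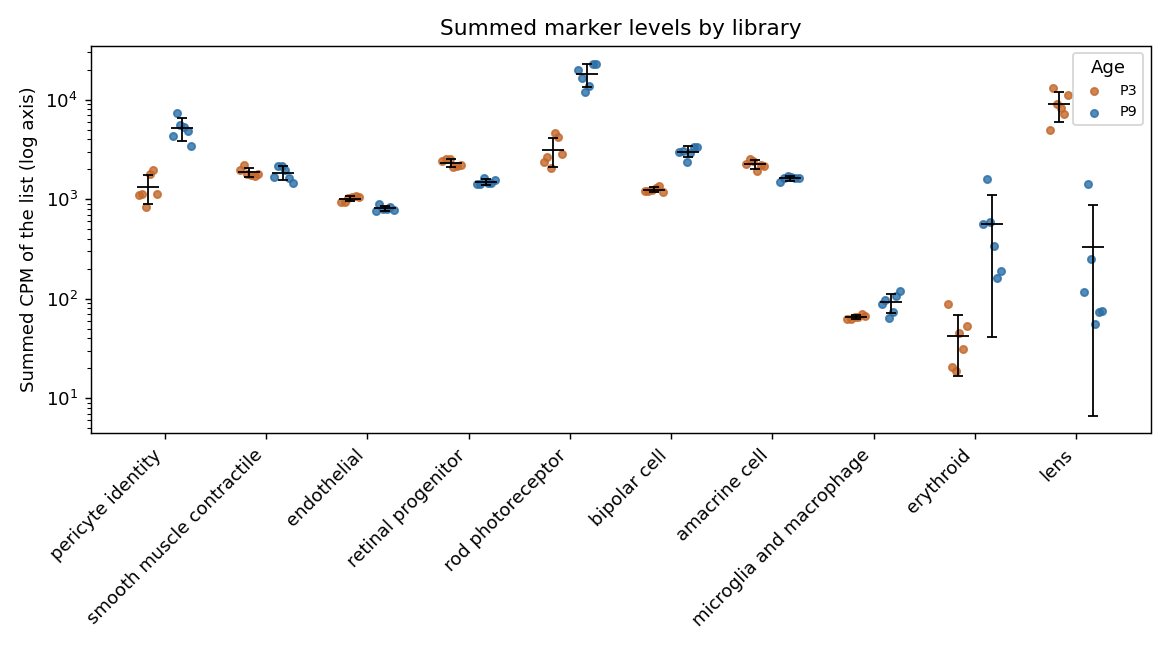
Summed CPM of marker lists on a log axis; each point is a library (6 per age), and the bars give the mean and SD, with lower ends that would pass below 0 drawn short. Rod markers go from a mean of 3122 to 17953 CPM and lens markers from 8966 to 334 CPM, while the smooth muscle sum is 1865 and 1852 CPM.

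The genes outside the lists of other cells that rose most included several of retinal neurons. Gabrr1 (chromosome 4, 33132556 to 33163588), a GABA receptor subunit of bipolar cells, rose 265-fold from 0.221 ± 0.146 to 58.9 ± 14.3 CPM (SD, n = 6 per age), and Bhlhe23, a bipolar cell transcription factor, 84.1-fold. Gucy2f, a photoreceptor guanylate cyclase, rose 20.9-fold and Cabp4, a calcium-binding protein of photoreceptor synapses, 19.5-fold. Trnp1, Fam135b and Susd3 rose 22.3-fold, 22.04-fold and 19.95-fold, and Mmp9, a matrix metalloproteinase, 24.97-fold to 23.3 ± 15.04 CPM. Vtn belongs to this set too. Of the 10 that fell most, Gli1 (chromosome 10, 127329882 to 127341579), a Hedgehog target, went from 37.2 ± 17.7 to 0.434 ± 0.380 CPM. Foxn4, a progenitor transcription factor, was 38.4-fold lower, with a log2 fold change of -5.26 that became -5.87 without P9 replicate 3. Next to the fall of the lens list, Capn3 was 46.5-fold lower, and the crystallin gene Crygn and the lens connexin gene Gja3 went from log2 fold changes of -5.30 and -4.58 to -6.15 and -5.19 without P9 replicate 2. Neil3, a DNA glycosylase, Sapcd2 and Nupr1 were 23.3-fold, 25.7-fold and 29.6-fold lower, and Mki67 52.3-fold lower. Krt15, an epithelial keratin, had a log2 fold change of -6.73. P3 replicate 1 held 662 CPM, and without that library the value was -2.998 (edgeR adjusted p = 0.000553). That value still includes P3 replicate 3, which held 27.9 CPM against 3.16 to 6.28 in the remaining P3 libraries. The Krt15 call was lost with limma-voom (log2 fold change -3.48, adjusted p = 0.174) and with its quality weights (-3.50, adjusted p = 0.132).

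Over the 36 lists, 15 were called higher and 6 lower at P9 by camera. With an estimated correlation, 1 was called higher (bipolar cell) and 1 lower (retinal progenitor). The fry test, which asks whether the genes of a list move on balance in a single direction, called 21 higher and 9 lower. Higher by fry and not called by camera were the fibrillar collagen, astrocyte, horizontal cell, microglia, immediate early and mitochondrial lists. Lower by fry and not called by camera were the PI3K, sterol synthesis and amacrine lists. The 37 splits drawn with 3 libraries of each age in both groups, a grouping made after seeing the data, gave up to 12 lists called in a direction.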

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

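Chosen only after the results were seen were the tests of the pericyte ratios to Pdgfrb, of a lower mural share, of the rod and amacrine difference, of the relation between pericyte and cell cycle levels, of the pericyte list beside the progenitor mean and of the splits by their balance of ages, and the genes Gli2 and Ptch1. A single library stood apart from the other 5 of its age in 26 of 332 groups of 6 values (7.83%), where its gap to the nearest other, as a share of the range, exceeded the 95% critical value of Dixon for 6 values. Chance marks about 1 in 20 groups. The values are in CPM. In P3 replicate 1 this held for Krt15 662 (others 3.16 to 27.9), Col14a1 41.2 (others 0.743 to 1.86) and Ptch1 111 (others 124 to 131). In P3 replicate 2 this held for Gli2 96.0 (others 31.8 to 54.1). In P3 replicate 3 this held for Smad5 211 (others 187 to 195), Xist 17570 (others 7.03 to 3754) and the sex linked sum 17570 (others 569 to 3756). In P3 replicate 4 this held for Lhx2 101 (others 106 to 109) and Arr3 29.2 (others 16.8 to 20.6). In P3 replicate 5 this held for Aqp4 3.30 (others 1.29 to 1.93) and Opn1mw 0.246 (others 0 to 0.0388). In P9 replicate 2 this held for Pdgfrb 1088 (others 457 to 682), Kcnj8 125 (others 51.0 to 74.7), Crygn 3.30 (others 0.121 to 1.09), Nid2 70.4 (others 34.6 to 46.6), Hbb-bt 92 (others 5.34 to 35.8), Hbb-bs 746 (others 66.7 to 256), Xist 6770 (others 2.94 to 2483), the erythroid sum 1585 (others 160.4 to 586), the lens sum 1431 (others 56.4 to 249) and the sex linked sum 6771 (others 464 to 2636). In P9 replicate 3 this held for E2f1 10.9 (others 4.74 to 6.42), Rbl1 21.8 (others 12.3 to 15.7), Dll1 34.7 (others 19.4 to 22.2), Sfrp1 21.2 (others 5.86 to 9.15) and Grm6 436 (others 552 to 595).

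Of 462 ways to split the 12 libraries into groups of 6, 100 were tested, the real split included. For the 4868 genes that rose and the 4779 that fell, 1 of the 100 splits, the real one, gave as many in a direction. The highest of the others gave 2404. The same held for the 3357 genes changed at least 2-fold (1 of 100, highest other 1223). The real grouping therefore stands apart from the others drawn, if the libraries are independent. Splits that mix the ages put the age difference into the spread within groups, so these counts do not exclude chance for single genes. For the number of higher lists this count does not exclude chance, with 15 in the real split, at least as many in 6 of 100 splits and 18 as the highest other. Of the others that reached it, 4 hold 5 libraries of the same age on a side and 1 holds 4, so they carry part of the age difference. The 37 splits with 3 libraries of each age on both sides gave up to 12 lists in a direction, so list calls at the preset correlation also arise where the ages are balanced. For the 6 lower lists the count (74 of 100, highest other 18) takes the larger direction of each split, which the real split meets through its higher lists, so it says nothing about chance.

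The cell cycle genes fell with the retinal progenitor genes. RNA of dividing progenitors carried through the immunoprecipitation was written down beforehand as an explanation, with values it would need. Both were met: over the 6 P3 libraries the means of these lists moved together (Spearman rho 0.943, n = 6, exact permutation p = 0.0333 adjusted over the 4 relations examined), and with the progenitor mean in the model the median log2 fold change of the cell cycle list was 0.081. Over the 6 P9 libraries rho was 0.0857 (adjusted exact permutation p = 0.919). P3 replicates 4 and 5, the closest P3 pair, had cell cycle means of 5.57 and 5.57 (others 6.11 to 6.49). Their progenitor means were 6.01 and 5.95 (others 6.12 to 6.28). Pericyte means were 4.10 and 4.17 (others 2.67 to 3.47) and rod means 6.32 and 6.14 (others 4.95 to 5.575). The P3 relations rest partly on this pair, and their p-values take the 6 libraries as independent. Over the 6 P3 libraries the pericyte and cell cycle means moved in opposite directions (rho -1, adjusted exact permutation p = 0.0111). Carried-over progenitor RNA would also give this where it and mural RNA trade shares, so the value does not weaken that explanation. A comparison added after these values were seen keeps the reading open, since the pericyte list, which rose, also went to 0.11 in that model and the mean shares 97.5% of its variance with age. Less division of mural cells and less progenitor RNA therefore cannot be told apart for these genes, and a difference in age itself stays open, untested.

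The rod genes rose more than those of amacrine cells, ganglion cells and microglia. With unchanged levels per cell, a larger share of other retinal cells in general would raise their lists alike. Neither bound written down beforehand was met, with medians of -0.27 for amacrine, 0.46 for ganglion cells and 0.43 for microglia. The rod and amacrine means, compared after these medians were seen, moved apart by 3.47 on the log2 scale. The SD of their difference was 0.54 at P3 and 0.61 at P9. That argues only against a general rise with unchanged levels per cell as the whole cause. Levels per rod or amacrine cell were not measured, so a general rise beside changed levels stays open. With unchanged levels per mural cell, a lower share of mural RNA would lower the pericyte list, whose median was 1.996. Levels per mural cell were not measured, so the direction of that list cannot exclude a lower share. Growth of the rod population or of rod transcript levels with age stays open, untested.

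The pericyte genes might rise through a larger share of mural RNA alone, which would leave their ratios to Pdgfrb alike. Of 23 members, 15 had a ratio that differed by age, 5 higher and 10 lower, with log2 differences of 1.32 for Kcnj8, 1.92 for Vtn, -2.08 for Heyl and -2.07 for Mcam. Both the test and the wording of its bound were set after the values were seen. No library here measures how much of these transcripts came from other retinal cells, so a change per mural cell and a change of share cannot be told apart for this list. An effect of age on mural cells stays open, untested, and the longer time from tamoxifen to harvest at P9 cannot be separated from it.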

How the results depend on the processing

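Leaving out P3 replicates 4 and 5 or P9 replicates 5 and 6, and the Y-linked and lens covariates, were tests chosen after seeing the data. With factors, filters, tools, left-out libraries, the surrogate variable and list rules changed 1 at a time, outside the covariates and the estimated correlation, 3517 values of named genes kept direction and side of the threshold, 40 lost the call, 0 gained it and 2 reversed. For lists these were 864, 37, 30 and 0, and for marker classes 399, 8, 8 and 3. Most named genes were picked for a small adjusted p or a large change without overlap, so few could gain a call. The counts of named genes therefore cannot measure how firm the other called genes are. Leaving out each library in turn gave 4515 to 5052 genes that rose, 4421 to 4747 that fell, 3124 to 3541 changed at least 2-fold, 13 to 16 higher and 4 to 8 lower lists and 16 to 18 differing classes. A mean of at least 10 CPM, which tests fewer genes, left 1583 genes changed at least 2-fold. Apart from 1 library left out, covariates and fry, named genes that lost the call were, without a low-count filter Ptch1, with limma-voom Krt15 and Col14a1, with its quality weights Krt15 and Col14a1, with the robust fit Col14a1, with 1 surrogate variable Pik3ca, mt-Nd5, mt-Nd2 and Tbx2, without P3 replicates 4 and 5 Ptch1, and without P9 replicates 5 and 6 Pik3ca, Col14a1, mt-Nd6, mt-Nd5, mt-Nd2 and Tbx2. Lists that lost it were, with a mean of at least 10 CPM basement membrane, Wnt signalling, interferon response and antigen presentation and endothelial, with DESeq2 endothelial, with limma-voom cell cycle exit, Wnt signalling, retinal ganglion cell and retinal pigment epithelium and melanocyte, with its quality weights basement membrane, cell cycle exit, Wnt signalling, retinal ganglion cell and retinal pigment epithelium and melanocyte, with 1 surrogate variable retinal ganglion cell, with shared genes left out basement membrane, without P3 replicates 4 and 5 Wnt signalling, endothelial, retinal ganglion cell and erythroid, and without P9 replicates 5 and 6 cell cycle exit, Wnt signalling, glycolysis and hypoxia, retinal ganglion cell and retinal pigment epithelium and melanocyte. Lists that gained it were, without a low-count filter fibrillar collagen and matrix remodelling, ribosomal proteins, sterol synthesis and immediate early and heat shock, with limma-voom ribosomal proteins, sterol synthesis and the mitochondrial genes, with its quality weights ribosomal proteins, sterol synthesis and the mitochondrial genes, with 1 surrogate variable fibrillar collagen and matrix remodelling, and without P9 replicates 5 and 6 fibrillar collagen and matrix remodelling and sterol synthesis. With an estimated correlation 1 list was called higher and 1 lower. DESeq2 called 4940 genes higher and 5062 lower, limma-voom 4967 and 4811. DESeq2 gave no adjusted p for Col14a1 and Krt15. The robust fit and the adjusted p under 0.01 gave no separate value for the lists. Depth limits genes near 1 TMM-scaled CPM to about 25.8 to 38.5 counts per library.

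A covariate that moves with age takes part of the age difference with it: age shares 91.9% of the variance of the rod mean, 97.5% of the progenitor mean, 84.4% of the pericyte mean and 87.7% of the lens mean. Beyond that the cause was not tested. With the rod mean, 16 genes rose, 6 genes fell, 22 genes changed 2-fold, 10 lists were called higher and 10 lower; values that reversed were list adjusted p fibroblast 0.0111, Müller glia 0.00597, cone photoreceptor 0.851, retinal ganglion cell 0.331, microglia and macrophage 0.0381, mitochondrially encoded 1.32e-12. Genes that reversed had log2 fold changes of Pik3ca -0.16, Akt1 0.13, Krt15 8.59, Flna 0.48, Aldoc -0.17, Ogn 1.03, Col14a1 6.22, Car14 -0.24, Lyz2 -0.33, Ctss -0.30, Ier3 -0.040, mt-Nd6 -1.09, mt-Nd5 -1.10, mt-Nd2 -1.39, Hnrnph1 0.13, Hnrnpf -0.061, Stat2 0.30. With the progenitor mean, 0 genes rose, 0 genes fell, 0 genes changed 2-fold, 3 lists were called higher, 3 lists were called lower by edgeR, with 323 genes at an unadjusted p under 0.05; DESeq2 and limma-voom were not run with it. Reversed were list adjusted p pericyte identity 0.898, cell cycle 0.898, cell cycle exit 0.898, Wnt signalling 0.898, ion channels and transporters 0.898, interferon response and antigen presentation 0.398, endothelial 0.508, Müller glia 0.127, retinal progenitor 0.898, rod photoreceptor 0.117, retinal ganglion cell 0.127, microglia and macrophage 0.0234, mitochondrially encoded 3.07e-06. Genes that reversed had log2 fold changes of Pdgfrb -0.66, Rgs5 -0.64, Cspg4 -0.72, Abcc9 -1.70, Mki67 0.043, Pik3ca -0.32, Akt1 0.48, Mmp9 -1.55, Gucy2f -1.34, Krt15 0.50, Gli1 1.24, Foxn4 2.10, Rgs4 -0.42, Itga8 -1.38, Flna 0.47, Lamb2 0.30, Nid2 -0.051, E2f1 0.41, Rbl1 0.86, Fgfr1 0.044, Dll1 0.23, Igf1 -0.84, Sfrp1 1.77, Cacnb2 -0.44, Aldoc -0.39, Slc2a1 0.41, Ifitm3 -0.57, Oasl2 -0.16, B2m -0.36, Ogn 1.66, Col14a1 2.83, Fabp7 0.0067, Aqp4 -3.22, Aldh1l1 -0.97, Car14 -0.013, Slc24a1 -0.29, Pde6a -0.58, Opn1mw -0.47, Gad2 0.10, Calb1 -0.59, Nefh -1.33, Thy1 -0.29, Lyz2 -3.02, Ier3 -0.69, mt-Nd6 -1.32, mt-Nd5 -1.39, mt-Nd2 -1.69, Hnrnph1 0.31, Tbx2 0.58, Stat2 0.32. With the pericyte mean, 559 genes rose, 530 genes fell, 864 genes changed 2-fold, 8 lists were called higher and 8 lower; reversed were list adjusted p pericyte identity 0.881, smooth muscle contractile 0.948, basement membrane 0.114. Genes that reversed had log2 fold changes of Rgs5 -0.57, Cspg4 -0.40, Notch3 -0.28, Acta2 -1.01, mt-Nd5 -0.012, Stat2 0.13. With the lens mean, 701 genes rose, 240 genes fell, 888 genes changed 2-fold, 14 lists were called higher and 5 lower; reversed were list adjusted p PDGF and FGF signalling 0.0425, lens 0.674. Genes that reversed had log2 fold changes of Ogn 0.52, mt-Nd6 -0.24, mt-Nd5 -0.31, mt-Nd2 -0.47.

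The log2 fold change of Col14a1 reversed to 0.73 with 1 surrogate variable and to 0.23 without P3 replicate 1, which held 41.2 CPM of that transcript. With each library left out in turn it ran from -2.78 to 0.23. The mean of log2(CPM + 1), which weighs members alike in place of the most abundant, reversed the class log2 differences of smooth muscle contractile 1.07, endothelial 0.79, astrocyte 0.56.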

Other observations

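The genes, groups and tests here were all chosen after the values were seen. Several Hedgehog pathway genes fell at P9, in a group put together after the values were seen: of 12 tested, 9 fell, 0 rose and 3 did not pass (9 fell adjusted over the group alone), with a median log2 fold change of -1.03. Gli2, a transcription factor of the pathway, went from 50.7 ± 23.8 to 5.14 ± 1.76 CPM (SD, n = 6 per age), and Gli3, its relative, from 112 ± 24.3 to 18.7 ± 4.14 CPM. Hhip, which binds Hedgehog ligands, fell from 7.88 ± 1.90 to 0.797 ± 0.377 CPM and Smo, the signal transducer at the membrane, from 90.05 ± 2.05 to 37.3 ± 6.04 CPM. The receptor gene Ptch1 was at 125 ± 7.64 and 108 ± 10.5 CPM (adjusted p = 0.0319), a call lost without P3 replicate 4, 5 or 6 or P9 replicate 1, 3 or 4 (adjusted p of 0.0720, 0.0584, 0.0629, 0.0526, 0.0732 and 0.0765). Progenitor markers, with a median log2 fold change of -1.93, fell in the same libraries.

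Among genes of splicing factors of the hnRNP and SR families, 16 of 31 fell, 2 rose and 13 did not pass (median log2 fold change -0.19). Hnrnph1 went from 2097 ± 453 to 937 ± 79.7 CPM and Hnrnpa1, which has many processed copies and is uncertain, from 763 ± 48.8 to 447 ± 44.2 CPM, while Hnrnpf rose from 249.6 ± 22.7 to 302 ± 13.8 CPM. Of long noncoding RNAs, Miat fell from 5844 ± 1422 to 562 ± 209 CPM and Malat1 from 1271 ± 253 to 823 ± 80.8 CPM. Meg3 was at 2426 ± 495 and 2338 ± 337 CPM (edgeR adjusted p = 0.766). How much of these transcripts was bound to tagged ribosomes was not measured. The fall of the progenitor markers in the same libraries stands beside these values too.

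P3 replicate 1 held the highest level of all 15 genes examined of corneal epithelium (5), skeletal muscle (6) and fibroblast matrix (4). Krt5 stood at 552 CPM there and at most 43.7 in another P3 library and 0.186 at P9. Krt12 was at 79.4 against at most 1.93 and 0.662, Acta1 at 148 against 5.16 and 1.75, and Col1a1 at 196 against 22.9 and 39.1. Replicate 3 came next among P3 libraries for Krt5 (43.7), Krt14 (21.5), Krt15 (27.9), Myh8 (11.2) and Acta1 (5.16), though not for Krt12 or Col1a2. The lens crystallin gene Cryaa was at 1807 CPM or more in the P3 libraries and at most 472 CPM, in replicate 2, at P9.

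Xist stood at 17570 and 3754 CPM in P3 replicates 3 and 4 and at 6770 in P9 replicate 2, where the Y-linked Eif2s3y was at 1.20, 0.238 and 0.441 CPM. In P9 replicates 5 and 6 Xist was at 2483 and 1190 CPM and Eif2s3y at 84.8 and 143 CPM. Transcripts of both kinds stand together in these 2 libraries, so the values do not show that each is a single animal. Without these 2 libraries 4099 genes rose and 4022 fell, and with the mean of the Y-linked genes in the model 4785 rose and 4685 fell.

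Over the 6 P3 libraries the mean log2 CPM of the pericyte list went down as that of the cell cycle list went up. Pearson r was -0.983 (exact permutation adjusted p = 0.00556). Without replicates 3 and 5, the 2 farthest from the median of the pericyte means, r was -0.996. That subset keeps replicate 4 (pericyte mean 4.10, others kept 3.25 to 3.47), the closest match of replicate 5. It therefore cannot show whether the relation rests on replicates 4 and 5. Over the 6 P9 libraries r was 0.779 (exact permutation adjusted p = 0.0778). For the progenitor and cell cycle lists r was 0.975 at P3 and 0.386 at P9 (exact permutation adjusted p of 0.0139 and 0.474).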
